A study of Mus musculus with 3 samples.

How the data were processed

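RNA was measured by sequencing in 3 libraries of UNSCC680, a mouse lung squamous cell carcinoma line, grown in culture and sampled at a single time point. Per the labels, 1 library came from control cells carrying an empty vector with a non-targeting sequence and GFP, and 2 libraries came from cells mutated in Pten with CRISPR-Cas9. Total RNA was extracted and libraries were prepared with the NEBNext Ultra RNA kit, per the labels' protocols, which do not state whether strand was kept. The submitters' processing notes name CASAVA 1.8 and the mouse genome build mm10. The aligner, the counting program and the gene annotation are not given in the sources used here.

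The authors deposited a single table of raw read counts per gene, which names 55335 genes by Ensembl identifier and symbol and gives a genome position for each. The 3 columns hold whole numbers summing to different totals, and each column name matched 1 sample's title. The table held 0 other columns of per-sample values. Of its symbols, 27 had been turned into dates by a spreadsheet and were mended through the gene identifier. Of the identifiers, 54587 were also in GENCODE M21, an annotation of the same genome build, and all of these had the same position there (98.6% of the table).

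Counts were analysed as deposited. Library totals were 20055259 in the control and 20064296 and 23182239 in the libraries labelled PTEN-null 1 and 2. CPM values are counts relative to library size, scaled by TMM normalization factors of 1.04, 0.990 and 0.974. The counts of the 2 libraries labelled PTEN-null were compared over 13451 genes with at least 20 counts in the pair, and chi-square divided by its degrees of freedom was 23.2, well above sampling noise, so they entered as separate libraries. The labels do not say whether they are separate clones or cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Counting intervals and floors below cover counting error only, since reads carry no molecular identifiers.

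Before the data were examined, the groups, the tests, 38 gene lists, the rule for naming genes and a set of alternative settings were fixed. Genes were filtered with filterByExpr, which left 14337 of the 26558 genes with any count, and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard error of a log2 fold change was derived from the F statistic of that test. With 1 control library, the spread came from the 2 libraries labelled PTEN-null alone, with 1 residual degree of freedom moderated by 14.0 prior degrees of freedom, and the control was assumed to vary like them. The common biological coefficient of variation was 0.131. A second count used no test: genes with a mean of at least 1 CPM whose ratio to the control, with 0.5 CPM added to both, was at least 2-fold on the same side in both libraries.

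Gene lists with at least 5 tested members (33 of the 38) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. That test compares the members of a list with all other genes. Its p-values thus take genes, not libraries, as replicates and do not measure variation between cultures. The same lists were also tested with camera at an estimated correlation and with fry. With 1 residual degree of freedom, that estimate rests only on which of the 2 libraries labelled PTEN-null each member was higher in. The test with it has 1 degree of freedom, so its p-values, given below for each list, can hardly be small whatever the list. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. A list's median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A further 3 lists, of smooth muscle contractile genes, endoplasmic reticulum chaperones, and interferons with their receptors and nucleic acid sensors, were added after the results had been seen. Pten was named first. The 10 genes with the highest and the 10 with the lowest fitted fold change were then named among genes past the threshold with a mean of at least 5 CPM that lay on the same side of the control in both libraries. Numbered gene models and pseudogenes were counted but not named. Each list contributed up to 4 members past the threshold with the largest absolute log2 fold change, or up to 2 of its most abundant members where none passed. Genes at 0 counts in a group are given a fold against a floor of 3 counts over that group, and genes with 1 to 3 counts an exact 95% binomial interval of the ratio.

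The scripts were tested on simulated data, 10 times, with the real genes, library sizes and means of this comparison (14337 genes in the fit). In each simulation 200 genes were changed. Every simulated library, the control included, had the dispersion fitted to the real data, which rests on the libraries labelled PTEN-null. The rates below therefore hold only if a control culture varies as those libraries do. They also belong to 200 changed genes, whereas the real data gave 3698 calls. The Benjamini-Hochberg cutoff depends on that number, so recovery in the real data can differ. The edgeR test recovered 14.1% of genes changed 1.5-fold, 57.8% of those changed 2-fold and 87.3% of those changed 4-fold, and 5.45% of its calls were unchanged genes. With no change simulated it called 0.1 genes on average. A simulated list of 30 genes raised 2-fold passed camera at the preset correlation in 10 of 10 simulations, in 0 with an estimated correlation and in 0 with fry. Camera called 1 of 300 unchanged lists. Simulated genes varied independently and those lists were random, so this says nothing of lists whose members move together.

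Alternatives covered RLE size factors, library totals without further scaling, no filter on low counts, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, fixed coefficients of variation of 0.1, 0.2 and 0.4, a stricter threshold of 0.01, a minimum log2 fold change of 1, other pseudocounts (0.1 and 2 CPM) and a minimum of 5 CPM for the count without a test, and leaving out each library labelled PTEN-null. The newer form of the quasi-likelihood fit, a fit without the 50 most abundant genes and a fit of nuclear protein-coding genes only were added after the data were seen. Figures were drawn with matplotlib 3.10.9. Reads of near-identical genes could have been split or dropped by the authors' counting, which concerns Ifit3 and Ifit3b, the H2-Q genes, the Oas1, Oasl and Mx families, Hspa1b, ribosomal protein genes with their pseudogenes, and mitochondrial genes with nuclear copies. Without a stated strand, reads of overlapping genes on opposite strands cannot be assigned.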

Results

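RNA sequencing compared UNSCC680 mouse lung squamous carcinoma cells carrying a control vector (1 library) with cells mutated in Pten by CRISPR-Cas9 (2 libraries). The title of the series places the comparison in work on PTEN loss, resistance to anti-PD-1 therapy and regulatory T cells, and the cells measured here were grown in vitro. Library totals ranged from 20055259 to 23182239 counts, with 21856 to 22308 genes detected per library. Fn1, which encodes the matrix protein fibronectin, was the most abundant gene in all 3 libraries, at 2.39% of counts in the control and 1.57% and 1.89% in the others. Values below are CPM as mean ± SD of the 2 libraries labelled PTEN-null, against the single control library, which has no replicate, and log2 fold changes are given ± SE from edgeR.

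The targeted gene, Pten (ENSMUSG00000013663.7, mm10 chromosome 19, 32757497 to 32826160, plus strand), encodes the lipid phosphatase that opposes PI3K. Its mRNA was not lower in the libraries labelled PTEN-null: counts were 8779 in the control and 13668 and 12655 in libraries 1 and 2. Pten stood at 423 CPM in the control and 625 ± 89.9 CPM (n = 2) in the libraries labelled PTEN-null, a log2 fold change of 0.56 ± 0.19 with an edgeR adjusted p of 0.0375. That call was lost with RLE size factors (adjusted p = 0.0518), with library totals alone (log2 fold change 0.49, adjusted p = 0.0850) and with DESeq2 (adjusted p = 0.0518). Gene counts do not show the edit itself, and a frameshift need not lower the mRNA, so the level of Pten mRNA neither establishes nor excludes the genotype given in the labels. Directions below are therefore those of the libraries labelled PTEN-null. Of the 33 tested components of the PTEN-PI3K-AKT-mTOR pathway, 3 were higher, 4 were lower and 26 did not pass the test, with 3 and 4 also adjusted over the list alone. Besides Pten, Pik3r3, a regulatory subunit of PI3K, was higher (log2 fold change 1.25 ± 0.30), as was Deptor, an inhibitor of mTOR (1.06 ± 0.17). Pik3r2 (-0.72 ± 0.15) and the translation repressor Eif4ebp2 (-0.90 ± 0.17) were lower. The list as a whole did not pass camera (median -0.02, adjusted p = 0.647).

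The libraries labelled PTEN-null differed from the control in 3698 of 14337 tested genes (25.8%), of which 1991 were higher and 1707 lower. Which direction held the majority depended on the scaling, since library totals alone gave 1580 higher and 2007 lower. All 3698 lay on the same side of the control in both libraries, 3407 were protein coding and 184 were long non-coding RNAs. Without any test, 709 genes were at least 2-fold higher and 413 at least 2-fold lower in both libraries, out of 12151 genes at 1 CPM or more. Simulated libraries with no change gave means of 4.9 and 1.6 such genes. Their control varied only as the libraries labelled PTEN-null do, so these means leave out any further difference between cultures. Between the 2 libraries labelled PTEN-null, 115 genes were at least 2-fold apart, against 1486 and 1545 between each of them and the control. The number of changed genes depends on the spread assumed, which the lone control cannot give. It was 1937 with a fixed coefficient of variation of 0.2 and 381 with one of 0.4. Both were set for all 3 libraries, with a likelihood-ratio test in place of the quasi-likelihood test. With DESeq2, which also differs in filter and scaling, the number of changed genes was 2029, and the cause of that difference was not tested.

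Among genes with a mean of at least 5 CPM, 9 of the 10 largest rises were in genes below 1 CPM in the control. Alcam, a cell adhesion molecule of the immunoglobulin family, had 0 counts in the control and 91.4 ± 11.2 CPM (n = 2) in the libraries labelled PTEN-null, at least 636-fold higher. The small GTPase Gem also had 0 counts in the control and was at least 74.6-fold higher. Postn, which encodes the matrix protein periostin, rose from 55.1 to 3433 ± 235 CPM, a 62.3-fold difference (log2 fold change 5.96 ± 0.26, edgeR adjusted p = 1.54e-09). The others among the 10 highest were Herc3 (log2 fold change 6.54), Enpp1 (6.23), Rab38 (5.98), Mpped2 (5.89), the WNT-potentiating secreted factor Rspo2 (5.50), the Rho-family GTPase Rhoj (5.44) and Ralgps2. Ralgps2 had 3 counts in the control, and its ratio was 76.3 with a 95% counting interval of 25.9 to 371.

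Among the 10 deepest falls were transcriptional regulators and basement membrane collagen IV. Id4, an inhibitor of basic helix-loop-helix factors, fell from 203 to 0.876 ± 0.455 CPM (log2 fold change -7.82 ± 0.24, edgeR adjusted p = 4.05e-11). Dach2, a transcriptional cofactor, had 519 counts in the control and 1 in the other libraries together, a ratio of control to the libraries labelled PTEN-null of 1059 with a 95% counting interval of 189 to 41918. Col4a2 (log2 fold change -6.57) and Col4a1 (-6.00), the main collagen IV chains, fell 95.2-fold and 64.1-fold, and the transcription factor Sox6 fell 68.5-fold (-6.10). These collagen genes lie head to head on chromosome 8 and overlap by their first bases on opposite strands, so that their counts are not wholly separable without strand. P2rx3, an ATP-gated channel (-5.47), Lratd2 (-5.46), Taf7l (-5.07), Ces2g (-3.95) and Tmem176b (-3.86) made up the rest of the 10 lowest.

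**Figure D1:**
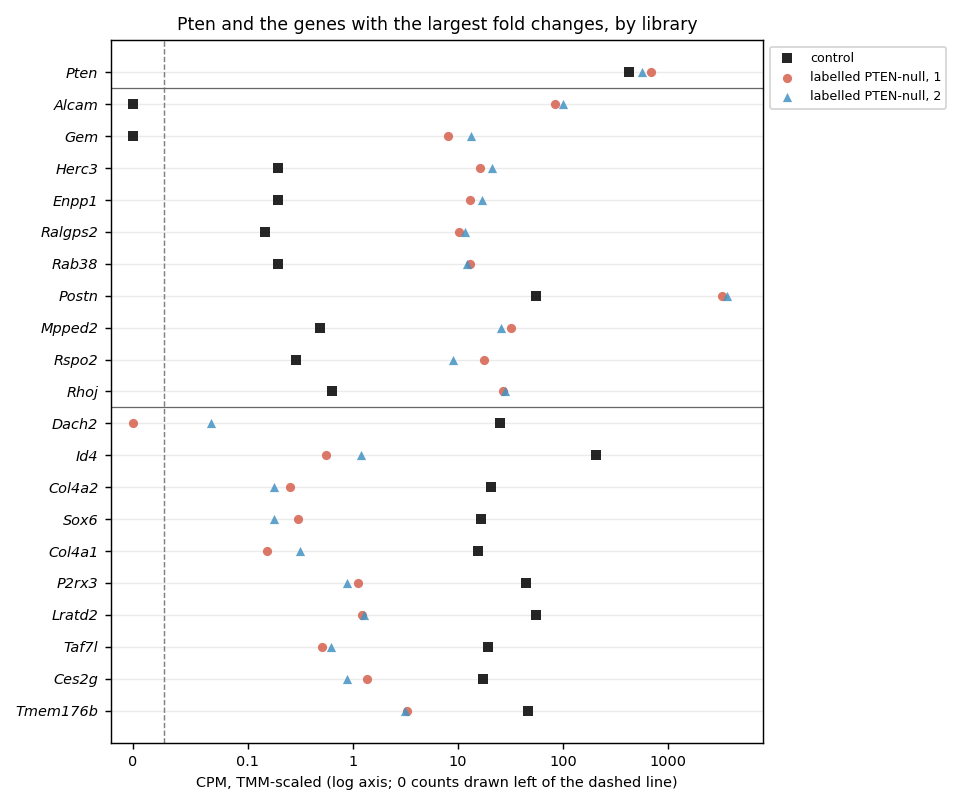
CPM on a log axis of Pten and of the 10 highest and 10 lowest named genes in each of the 3 libraries, with the control as squares, the libraries labelled PTEN-null 1 and 2 as circles and triangles, and values of 0 counts left of the dashed line. Apart from Pten, the symbols of both libraries lie far from the control, with Alcam at 0 in the control and at 83.5 and 99.3 CPM in libraries 1 and 2, while some also lie apart from each other, such as Rspo2 at 17.7 and 8.96 CPM and Id4 at 0.554 and 1.20 CPM.

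Interferon-stimulated genes were higher almost throughout. Of 47 tested, 45 rose, 0 fell and 2 did not pass, over all genes and likewise adjusted over the list alone. Their median log2 fold change was 1.61, a 3.04-fold difference. The antiviral synthetase gene Oas3 rose from 1.64 to 52.1 ± 7.03 CPM (log2 fold change 4.99 ± 0.28), Cmpk2 rose 24.7-fold, the antiviral gene Rsad2 23.3-fold and the GTPase gene Iigp1 11.7-fold. The members that did not pass were Gbp4 (0.11) and Ifi27 (-0.30). Camera placed the list above the other genes (adjusted p = 2.84e-47). The call was lost at adjusted p = 0.661 by camera with an estimated correlation (-0.02), a test that no list passed here. Leukocyte markers, summed over 20 genes, stood at 4.72 CPM in the control and at 9.87 and 6.70 CPM in libraries 1 and 2.

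MHC class I antigen presentation genes were also higher: 15 of 22 rose and 0 fell, with 15 and 0 adjusted over the list alone, and the median was 1.16. The class I heavy chain H2-K1 rose from 87.9 to 339 ± 17.1 CPM (log2 fold change 1.95 ± 0.18). The immunoproteasome subunit Psmb9 (2.34 ± 0.37), the peptide-loading protein Tapbp (1.68 ± 0.18) and H2-Q4 (1.67 ± 0.20) rose too, while the immunoproteasome subunit Psmb8 stood at -1.32 without passing. The list passed camera (adjusted p = 9.99e-10), but gave adjusted p = 0.688 with an estimated correlation. Only 4 MHC class II genes were tested, too few for a list test, and H2-DMb2 was lower (-1.14 ± 0.40). Immune checkpoint ligands went both ways: 5 of 20 were higher and 5 lower (5 and 6 adjusted over the list alone), and the list did not pass (median -0.10, adjusted p = 0.965). Among them Cd24a rose 13.5-fold and Tnfsf10, which encodes the death ligand TRAIL, 4.16-fold. Cd80, a costimulatory ligand of T cells, fell from 47.0 to 3.78 ± 0.428 CPM, and Vtcn1 fell from 14 counts to 3 over both libraries, a ratio of control to the others of 9.52 with a 95% counting interval of 2.66 to 51.7. Cd274, which encodes PD-L1 and was singled out after its values were seen, had a log2 fold change of -0.97 and did not pass (adjusted p = 0.0780).

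Factors that recruit or promote regulatory T cells were in part higher: 6 of 20 tested rose, 0 fell and 14 did not pass (6 and 1 adjusted over the list alone). The chemokine Cxcl12 rose from 414 to 1584 ± 656 CPM (log2 fold change 1.94 ± 0.29), the prostaglandin E synthase Ptges rose 2.91-fold, Tgfb3 2.72-fold and the chemokine Ccl28 3.63-fold, from 0.722 to 2.63 ± 0.163 CPM. The other 2 that rose, named beyond the rule, were Ccl17 (1.40) and Tgfb1 (0.63). Ccl22 had 0 counts in all 3 libraries. As a list these factors did not pass camera (median 0.48, adjusted p = 0.182), though the median lay at percentile 98.7 of random lists. It was 0.68 without library 1 and 0.31 without library 2. Of 30 myeloid chemokines and inflammatory cytokines 14 were tested. Of these, 6 were higher and 0 lower, with the same counts adjusted over the list alone and a median of 0.62. Cxcl15, a neutrophil chemokine, rose from 2.89 to 110 ± 28.5 CPM, Il6 rose 9.24-fold, Ccl7 3.87-fold and Ccl2 2.98-fold, the latter 3 at under 5 CPM. This list passed camera (adjusted p = 8.90e-04), against adjusted p = 0.787 with an estimated correlation. Of 13 chemokines that attract T and NK cells 5 were tested. Of these, 2 rose and 0 fell (2 and 1 adjusted over the list alone), Cxcl10 by 1.68 ± 0.33 and Cx3cl1 by 0.51 ± 0.16 on the log2 scale. That list did not pass camera (median 0.45, adjusted p = 0.510). NF-kB targets had 6 of 21 members higher and 0 lower by either adjustment (adjusted over the list alone 6 and 0), among them Bcl3 (2.12), Birc3 (1.39) and Rel (1.01) besides Il6, and the list did not pass (median 0.13, adjusted p = 0.182).

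Genes of lipid synthesis were higher. In cholesterol biosynthesis 23 of 24 genes rose and 0 fell, also when adjusted over the list alone, with a median of 2.31, a 4.97-fold difference. Tm7sf2, a sterol reductase, rose from 6.88 to 48.7 ± 3.59 CPM, and Idi1, Fdps and Pmvk, enzymes of the mevalonate route, rose 7.74-fold, 6.67-fold and 6.10-fold. Pcsk9, with 2 counts in the control, was the member that did not pass. In fatty acid synthesis 16 of 18 genes rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 1.14. Acss2, which makes acetyl-CoA from acetate, rose 7.11-fold, the desaturases Scd2 and Scd1 rose 3.85-fold and 3.69-fold, and the elongase Elovl6 3.54-fold. By camera, adjusted p was 6.51e-45 for cholesterol and 2.11e-13 for fatty acid synthesis. These became adjusted p = 0.661 and adjusted p = 0.787 with an estimated correlation.

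Glycolytic genes followed, with 14 of 21 higher and 0 lower (15 and 1 adjusted over the list alone) and a median of 0.74. Pfkfb3, a regulator of phosphofructokinase, rose from 10.8 to 68.0 ± 2.36 CPM, Pdk1, a kinase that restrains pyruvate dehydrogenase, rose 3.40-fold, Pfkp 2.41-fold and Pgk1 2.39-fold. Hypoxia response genes had 9 of 19 members higher and 0 lower, also when adjusted over the list alone (median 0.80), with P4ha2 (log2 fold change 2.00), Car9 (1.94) and P4ha1 (1.59) beside Pdk1. Both lists passed camera (adjusted p = 1.33e-05 and 1.05e-03), with adjusted p = 0.688 for both lists with an estimated correlation. Without a filter on low counts the hypoxia list lost its call (adjusted p = 0.0830) and so did the myeloid list (adjusted p = 0.0787). Mitosis genes rose together: 23 of 28 G2/M genes were higher and 0 lower (25 and 0 adjusted over the list alone), with a median of 0.71 and with Aurkb (1.47 ± 0.20), Cdk1 (1.25 ± 0.18), Ccnb1 (1.15 ± 0.20) and Bub1b (1.09 ± 0.18) in front. The call (adjusted p = 1.89e-08) became adjusted p = 0.787 with an estimated correlation. DNA replication and S phase genes did not pass as a list (adjusted p = 0.979), with 1 of 33 higher, Rrm2 at 0.75 ± 0.26, and 1 lower, Mcm7 at -1.35 ± 0.21 (0 and 1 adjusted over the list alone). Its median was 0.12 and its mean 0.07, against a test direction of down.

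Many mesenchymal genes were higher, and some squamous genes were lower. Of 24 mesenchymal genes 12 rose, 2 fell and 10 did not pass, with the same counts adjusted over the list alone and a median of 0.81. Col1a1 rose from 1093 to 12452 ± 251 CPM (11.4-fold), Acta2, smooth muscle actin, from 1323 to 5303 ± 28.0 CPM, and Fbn1 from 7.32 to 22.6 ± 9.67 CPM, beside Postn. The 2 that fell were S100a4 (-0.67) and Twist2 (-1.34). Fibroblast markers, listed to detect another cell type, moved with them: 7 of 9 rose and 1, Twist2, fell (7 and 2 adjusted over the list alone), with a median of 1.60. Lum rose 27.5-fold and Dcn 6.34-fold, while Thy1 and Fap had at most 1 count in any library and Pdgfra stood at -0.52. Of these 9 markers, 6 are also in the mesenchymal list. The markers summed to 3702 CPM in the control and to 21260 and 21180 CPM in libraries 1 and 2. TGF-beta targets had 9 of 18 members higher and 2 lower, also when adjusted over the list alone (median 0.53). Id2 rose 11.3-fold, from 7.17 to 51.6 and 110 CPM in libraries 1 and 2, beside Col1a1 and Ltbp2, whose ratio was 12.7 on 2 control counts with a 95% counting interval of 3.35 to 108, and Col4a1 was among those that fell. In camera, adjusted p was 1.12e-06 for mesenchymal genes, 4.16e-13 for fibroblast markers and 4.26e-06 for TGF-beta targets, and adjusted p = 0.688 for each with an estimated correlation. Without the 50 most abundant genes, 7 of them members, the mesenchymal list no longer passed (adjusted p = 0.0649), with a median of 0.64 over the 17 members left. Extracellular matrix and protease genes were split, with 9 of 26 higher and 5 lower by either adjustment (adjusted over the list alone 9 and 5). Adamts1 (2.52 ± 0.21) and the protease inhibitor Serpine1 (2.44 ± 0.20) rose while both collagen IV genes fell, and the list did not pass (adjusted p = 0.510; median 0.53, percentile 99.8 of random lists, mean -0.08, test direction up).

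Of 34 listed squamous keratinocyte lineage genes, only 11 passed the filter on low counts, so the values cover part of the list. Of these 11, 0 rose and 5 fell, also when adjusted over the list alone, with a median of -0.64. The plakophilin Pkp1 fell from 132 to 36.6 ± 8.75 CPM, the lineage factor Sox2 from 80.8 to 34.9 ± 2.01 CPM and Klf5 from 85.4 to 40.0 ± 15.7 CPM, and Pkp3 fell by 2.78 on the log2 scale from 1.64 CPM. Krt5 had 0 counts in all 3 libraries. The list passed camera at adjusted p = 2.10e-03, with adjusted p = 0.787 with an estimated correlation. Only 3 genes of terminal differentiation were tested, and of these Cdsn, which encodes corneodesmosin, fell from 291 to 50.2 ± 35.0 CPM and Krt10 fell by 1.27 on the log2 scale. Of 27 epithelial junction genes only 6 were tested, and of these 4 were lower and 1 higher (4 and 1 adjusted over the list alone). Cdh1, the E-cadherin gene (-2.64 ± 0.88, from 0.770 CPM), Krt8 (-1.81 ± 0.42) and Tjp2 (-1.44 ± 0.17) fell, and Krt18 rose (0.66 ± 0.23), without a list call (median -0.96, adjusted p = 0.0817).

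Output genes of the ERK pathway were lower, with 0 of 22 higher and 10 lower (1 and 12 adjusted over the list alone) and a median of -0.52. The EGFR ligand gene Areg fell 6.74-fold, from 74.3 to 6.80 and 15.1 CPM in libraries 1 and 2, the phosphatase Dusp4 fell from 19.3 to 3.53 ± 1.85 CPM, Etv4 from 27.9 to 8.04 ± 2.02 CPM and Hbegf from 44.3 to 14.1 ± 8.87 CPM. Camera gave adjusted p = 1.61e-05, and adjusted p = 0.787 with an estimated correlation. Egfr itself rose from 58.7 to 239 ± 28.7 CPM (4.07-fold), Fgfr2 rose 4.74-fold and Pdgfrb 2.25-fold, whereas the insulin receptor substrate Irs2 fell by 1.14 on the log2 scale. Among 19 receptor tyrosine kinases and adaptors 4 were higher and 2 lower (4 and 3 adjusted over the list alone), without a list call (adjusted p = 0.674; median -0.10, mean 0.14, test direction up). FOXO target genes, which PI3K signalling holds down, did not move as a list (adjusted p = 0.979, median -0.004252): 6 of 28 were higher and 5 lower (7 and 6 adjusted over the list alone). Txnip (-1.48 ± 0.37), Krt10 and Irs2 fell, and Sesn1 rose (1.19 ± 0.16).

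p53 target genes were lower: of 26 tested, 16 fell and 3 rose (17 and 6 adjusted over the list alone), with a median of -0.83. Cdkn1a, the p21 cell cycle inhibitor, fell from 375 to 90.9 ± 5.41 CPM, Ccng1 from 1252 to 429 ± 35.0 CPM and Eda2r from 137 to 42.9 ± 11.2 CPM, beside Cd80. Camera gave adjusted p = 8.34e-09, and adjusted p = 0.688 with an estimated correlation. Cytosolic ribosomal protein genes had 39 of 74 members lower and 1 higher (46 and 1 adjusted over the list alone), with a median of -0.62. The 4 past the test with the deepest falls were Rpl12 (-1.37 ± 0.20), Rpl21 (-1.06 ± 0.28), Rps10 (-1.05 ± 0.34) and Rpl27 (-1.03 ± 0.25), genes whose reads can be shared with pseudogenes. Of 13 mitochondrially encoded genes only 7 passed the filter on low counts. Of these, 6 were lower and 0 higher, also when adjusted over the list alone (median -0.72). The falls were led by mt-Cytb (-1.20 ± 0.19), mt-Nd4 (-1.04 ± 0.18), mt-Nd2 (-0.78 ± 0.18) and mt-Nd6 (-0.72 ± 0.18). Mitochondrial reads made up 2.71% of counts in the control and 1.62% and 1.89% in libraries 1 and 2. Camera gave adjusted p = 9.80e-10 for ribosomal and 1.05e-03 for mitochondrial genes, and adjusted p = 0.787 for both with an estimated correlation.

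The remaining lists did not pass camera. ATF4 targets and amino acid genes had 2 of 28 higher and 6 lower (4 and 6 adjusted over the list alone; median -0.21, adjusted p = 0.0787), with Atf5 (-1.60), the cystine transporter Slc7a11 (-1.43), Nupr1 (-1.15) and Sesn2 (-0.87) lower. Nuclear genes of oxidative phosphorylation had 2 of 34 higher, Ndufa1 (1.82) and Sdha (0.58), and 1 lower, Cyc1 (-0.46), against 1 and 0 adjusted over the list alone (median -0.20, adjusted p = 0.507). NRF2 targets had 5 of 26 higher and 4 lower (7 and 5 adjusted over the list alone; median 0.13, adjusted p = 0.497), with Osgin1 (1.68), Tkt (1.59) and Nqo1 (1.51) higher and Slc7a11 lower. Immediate early and heat shock genes had 6 of 18 higher, Fosb (2.33), Nr4a1 (1.20 ± 0.34, with log2 ratios of 0.42 in library 1 and 1.69 in library 2) and Hspa1b (1.06) among them, and 6 lower, Hsph1 (-1.01) among them, with 7 and 7 adjusted over the list alone (adjusted p = 0.965). Their median was -0.26 and their mean 0.12, and the test direction was down. WNT targets had Wnt5a higher (1.20) and Ccnd1 (-0.84) and Myc (-0.80) lower among 8 tested (2 and 2 adjusted over the list alone; adjusted p = 0.965; median -0.01, mean 0.36, test direction up). YAP targets had 3 of 16 higher, Ccn2 (1.92), F3 (1.63) and Ankrd1 (0.78), and 1 lower, Ajuba (-1.06), with the same counts adjusted over the list alone (median 0.17, adjusted p = 0.507). Alveolar and airway markers, of which 5 of 15 were tested, had 2 higher, Hopx (3.95) and Abca3 (0.84), and 0 lower, also when adjusted over the list alone (median 0.35, adjusted p = 0.430).

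**Figure D2:**
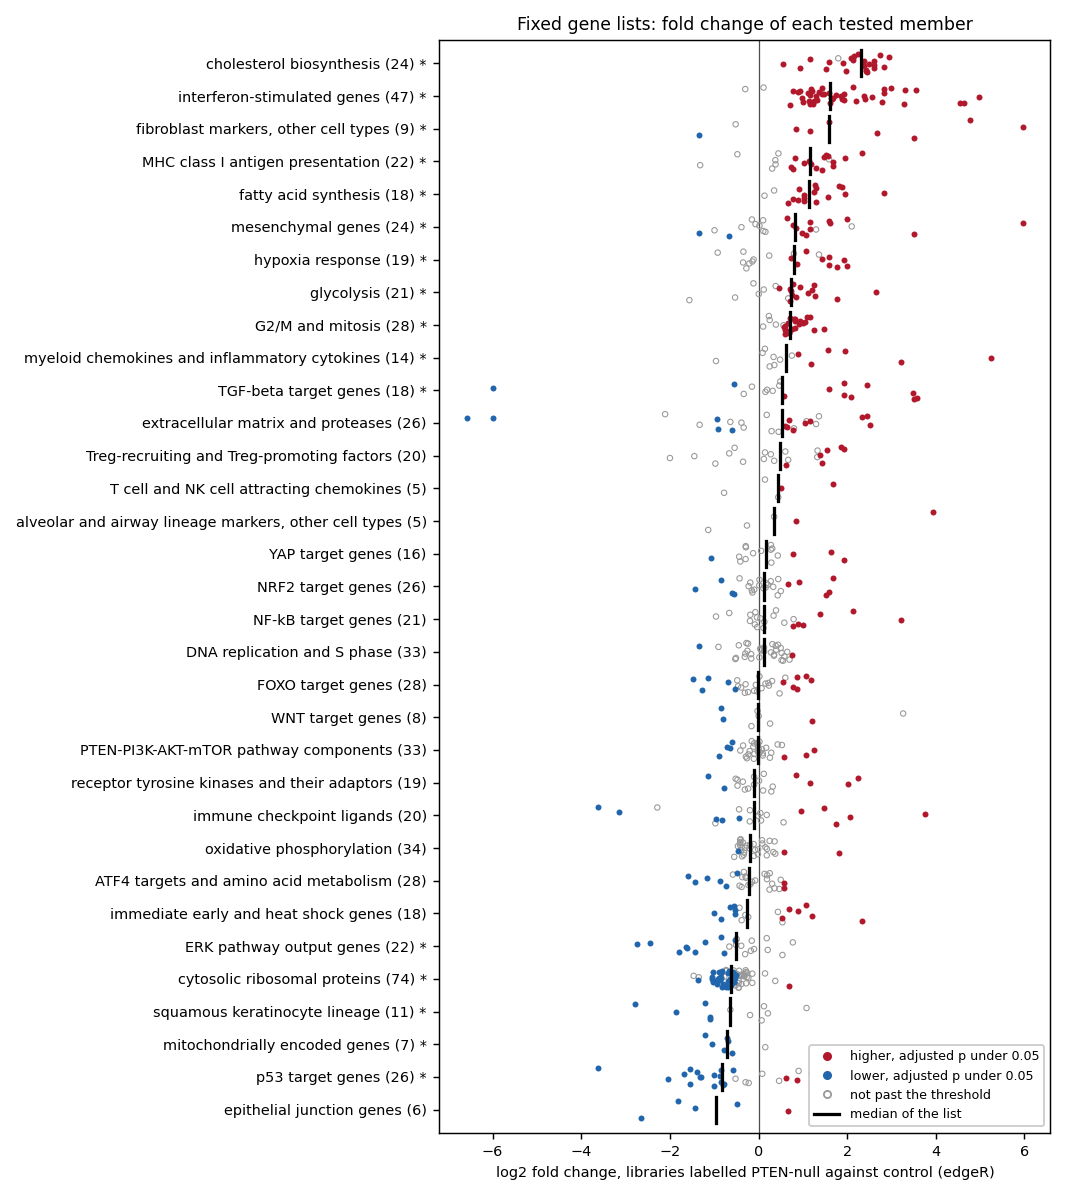
Log2 fold change of each tested member (points) of the 33 gene lists tested, ordered by the list's median (black bar), with red and blue for members past the edgeR threshold and higher or lower, open circles for the others, the number tested in brackets and an asterisk where camera at the preset correlation passed. Cholesterol biosynthesis (median 2.31) and interferon-stimulated genes (1.61) lie highest, and p53 targets (-0.83) are the lowest list that passed.

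Endothelial and leukocyte markers had few reads, unlike the fibroblast markers above. Endothelial markers summed to 2.94 CPM in the control and 3.42 and 5.85 CPM in libraries 1 and 2, with Egfl7 at 0.63 ± 0.43 without passing and Vwf at 1 control count (ratio 11.3, 95% counting interval 1.83 to 464). The leukocyte markers Cd68 (0.93 ± 0.40) and Lyz2 (0.74 ± 0.51) did not pass, and Ptprc, which all leukocytes express, had 0 counts in all 3 libraries. X inactivation and Y-linked genes summed to under 1 CPM in every library, with 0.529 CPM in the control and 0.353 and 0.843 CPM in the others, and Xist did not pass (0.42 ± 0.79). In all, 16 of the 33 lists passed camera at the preset correlation, 11 upward and 5 downward, and all 16 medians lay outside the middle 95% of random lists matched on expression. So did the medians of 6 of the 17 lists that did not pass: besides regulatory T cell factors and extracellular matrix and proteases, whose median was 0.06 without library 2, these were epithelial junction genes (percentile 0.250), ATF4 targets (1.19), immediate early and heat shock genes (1.32) and oxidative phosphorylation (1.73). Medians of ATF4 targets and of immediate early and heat shock genes were -0.04 and -0.06 without library 1, and -0.31 and -0.47 without library 2. With camera at an estimated correlation 0 passed (smallest adjusted p = 0.661; 2 lists had an unadjusted p under 0.05), and with fry 0 passed (smallest adjusted p = 0.108; 3 lists unadjusted). Those tests also passed 0 of 10 simulated lists raised 2-fold at this design. The estimated correlation was below the preset 0.01 for interferon-stimulated (-0.02) and cholesterol (-0.04) genes, whose calls were lost as well. A call lost in that test is therefore no sign in itself that the members move together. Estimates were 1 for G2/M and mitochondrial, 0.78 for fatty acid, 0.64 for squamous, 0.45 for ribosomal and 0.38 for ERK output genes. In the other lists that passed they ran from -0.05 (hypoxia response) to 0.12 (myeloid). Where members do move together the preset 0.01 makes a call too strong, and an estimate from 2 libraries cannot settle for which lists.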

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

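The newer quasi-likelihood fit and the fits without the 50 most abundant genes and of nuclear protein-coding genes only were chosen after the results were seen. The number of changed genes (3698, with 1991 higher and 1707 lower) fell to 2035 (1172 and 863) at an adjusted p under 0.01 and to 1728 (1025 and 703) with a log2 fold change of at least 1, both stricter by construction. It was 2029 (1243 and 786) with DESeq2, of which 2027 were among the 3698 with the same direction; the cause was not tested. With the coefficient of variation fixed at 0.2 it was 1937 (1094 and 843), at 0.4 it was 381 (180 and 201) and at 0.1 it was 5396. Those fits set the same value for all genes in all 3 libraries and used a likelihood-ratio test. They therefore do not isolate the spread of a control that has 1 library. The count thus rests on the spread and the test assumed. It stayed within 1.5 times with RLE size factors (3290), library totals (3587), no filter (4080), a minimum mean of 1 CPM (2906), limma-voom (3502), the newer fit (3548), without the 50 most abundant genes (3627) and among nuclear protein-coding genes (3208). The share of changed genes that were higher was 53.8%, against 44.0% with library totals (1580 higher and 2007 lower), which lowered the median log2 fold change of all genes by 0.08, and 61.3% with DESeq2. The planned legacy form of the fit is the default of the installed version and changed nothing.

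Pten kept its direction in every fit but lost its call with DESeq2 (log2 fold change 0.56, adjusted p = 0.0518), RLE size factors (0.56, adjusted p = 0.0518), library totals (0.49, adjusted p = 0.0850), a minimum of 1 CPM (0.56, adjusted p = 0.0661) and coefficients of variation of 0.2 (0.56, adjusted p = 0.360) and 0.4 (0.56, adjusted p = 1.00), and without either library it was 0.41 to 0.70, values with no residual degrees of freedom for a test. Gene lists past the threshold numbered 16, and 0 with an estimated correlation and 0 with fry, tests that passed no simulated list of this design either. Genes at least 2-fold lower in both libraries numbered 413, against 232 at a minimum of 5 CPM, where fewer genes were considered, and 595 to 629 without either library labelled PTEN-null, where a single library had to pass. Of the 139 other named genes, none changed direction while called. The losses of a call, 158 over all settings, were mostly at a coefficient of variation of 0.4 (92), with DESeq2 (25, with 4 more left without an adjusted p) and at 0.2 (16). List medians lost their call in 3 cases: hypoxia response (median 0.74) and myeloid chemokines (0.42) without a filter, and mesenchymal genes (0.64) without the 50 most abundant genes. Without 1 library labelled PTEN-null, a further 17 list medians (8 without library 1, 9 without library 2) moved by more than the spread between libraries. That spread is the SD of the values without library 1 and without library 2, so a result midway between them cannot pass it. Among named genes, Pkp3 and Dach2 moved by more than the spread. The largest of these list moves were in extracellular matrix and proteases (0.53 to 0.06 without library 2) and, without library 1, in hypoxia response (0.80 to 0.54), TGF-beta targets (0.53 to 0.78) and glycolysis (0.74 to 0.52). In the other 10 lists, cholesterol biosynthesis, interferon-stimulated, mesenchymal, myeloid, checkpoint, NRF2, p53, oxidative phosphorylation, receptor tyrosine kinase and PTEN pathway genes, the move was under 0.2. Medians of 5 lists, none past the test, had opposite signs without library 1 and without library 2: DNA replication and S phase (-0.23 and 0.44), FOXO (0.15 and -0.14), WNT, YAP and receptor tyrosine kinases. Fold changes of 18 named genes moved by more than 1.5 times: Areg, Cdsn, Col4a1, Dusp4, Hbegf, Id2, Id4, Il6, Irs2, Ltbp2, Nr4a1, Pik3r3, Txnip, Vwf and those that follow. Pkp3 and Dach2 had 0 counts in library 1 (10 and 1 in library 2). Lyz2 and Xist, which did not pass the test, changed sign but stayed within the spread. No paired analysis was possible because there is 1 control library, whose title carries no replicate number. Depth limits genes near the floor of 3 counts. The recovery of 2-fold changes in simulation was 57.8%, with 200 genes changed against 3698 called in the real data. It therefore does not measure the effect of depth here.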

Other observations

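The lists of smooth muscle, endoplasmic reticulum and interferon pathway genes, the tests of each side of Pten, and the test of a smaller set of leukocyte genes were chosen after the results were seen. Smooth muscle contractile genes were higher in the libraries labelled PTEN-null: 8 of 15 tested rose and 1 fell (9 and 1 adjusted over the list alone), with a median log2 fold change of 1.61, which was the same with the 2 members at 0 control counts set at their bound. Besides Acta2, the leiomodin Lmod1 rose from 67 counts to 1253 and 1328 (4.24), Actg2 rose by 3.87, the myosin kinase gene Mylk by 1.67 and Smtn by 1.61 on the log2 scale. Myl9 and Myh11 had 0 control counts and were at least 10.1-fold and at least 3.43-fold higher. The intermediate filament gene Des fell by 2.38, while the abundant Cald1 (0.38) and Tpm1 (0.16) did not pass. Camera gave adjusted p = 2.07e-09 over the 3 added lists, and adjusted p = 0.457 with an estimated correlation (0.73). Because these lists were chosen from the same results, the p-values of the 3 added lists describe a rise and do not test it.

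Endoplasmic reticulum chaperones rose in the same libraries, 17 of 20 with 0 lower (19 and 0 adjusted over the list alone) and a median of 1.15. Sdf2l1 rose by 2.42, the disulfide isomerase Pdia4 by 1.97, Hsp90b1 by 1.89 and Hspa5, the main chaperone of that compartment, by 1.13, from 33548 counts to 55538 and 96410. Camera gave adjusted p = 2.04e-15, and adjusted p = 0.457 with an estimated correlation (0.62), again for a list chosen from these results. A list of interferons, their receptors and those nucleic acid sensors that were not already counted as interferon-stimulated had 3 of 13 higher and 0 lower (3 and 0 adjusted over the list alone) and no list call (median 0.09, adjusted p = 0.465). The sensors Zbp1 (2.40), Ifih1 (1.93), Ddx58 (1.60) and Eif2ak2 (1.26), counted among the interferon-stimulated genes, all rose. Tlr3 (0.68), Jak2 (0.58) and Tbk1 (0.50) rose, Ifnar1 (0.03) and Cgas (0.07) did not pass, and Ifnb1, which was not tested, had 0 counts in the control and 3 and 8 in libraries 1 and 2.

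Pten mRNA was higher, not lower, in the libraries labelled PTEN-null. Scaling does not account for this, since the lowest log2 fold change over other scalings and single libraries was 0.4094. A copy number gain around Pten is a candidate explanation: the 60 tested genes within 5 Mb had a median 0.5657 above that of all genes (bootstrap 95% interval 0.20 to 0.68), a value reached by 1 of 226 windows of 61 neighbouring genes. Those windows were laid end to end and not centred on Pten, so the comparison is not like for like. The windows with the highest medians, from 0.61 down to 0.38, did not hold Pten. After Pten the median was 0.57 without the Ifit genes clustered there (0.29 to 0.74, 25 genes) and before Pten it was 0.05549 (-0.13 to 0.59, 29 genes). Among genes at 5 CPM or more in the control, again without Ifit genes, it was 0.57 after Pten (0.19 to 0.69, 17 genes) and 0.21 before (-0.08 to 0.62, 20 genes). The genes kept after Pten included Acta2 (2.00), Ankrd1 (0.78), Kif11 (0.69) and Fas (0.62), members of the mesenchymal, YAP, G2/M and p53 lists. Whether such genes, rather than a gain, set that median was not tested. Neither side was even, with the abundant Tnks2 (-0.20), Btaf1 (-0.23), March5 (-0.09) and Ide (-0.06) after Pten and Atad1 (-0.21) next to it before. How far such a gain would reach on either side therefore stays open. Exchanged labels stay open because FOXO targets went both ways around a median of -0.004252, and an effect of the edit on the Pten transcript itself was not tested.

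Interferon-stimulated genes were higher in 45 of 47 cases. Leukocytes in the cultures are argued against by Ptprc, Laptm5, Tyrobp, Fcer1g, Cd3e and Cd79a, of which some mark single leukocyte types. These 6 genes had 16 counts in the 2 libraries labelled PTEN-null together and 9 in the control, while the rise itself amounted to 71229 and 83490 reads. The wider marker list, on which the test was planned, summed to 2.09 and 1.42 times the control and by the planned rule decided nothing. The rise was no feature of 1 library, since the lower of the 2 medians was 1.505. What raised these genes stays open, since with 1 control library the state of that culture and the mutation cannot be separated here.

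The higher levels of mesenchymal and smooth muscle genes could come from fibroblasts mixed into the cultures or from the tumour cells themselves. Of 9 fibroblast markers 7 rose, but Twist2 fell, Thy1 and Fap had at most 1 count and Pdgfra had 527 counts in the control and 295 and 464 in the others. Those values speak against ordinary fibroblasts without excluding a subtype, since no fibroblast profile is part of these data, and the 2 explanations cannot be told apart. Whether a few very abundant genes set the list's call stays open: without the 50 most abundant genes the adjusted p was 0.06494, but this removed 7 of the 24 mesenchymal genes, 5 of them called, and the median was 0.64 (quartiles -0.07 to 1.17) over the 17 left, against 0.81 over all.

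A hypothesis of chromosome-scale copy number differences between the control and the cells labelled PTEN-null was also tested. Chromosome medians lay outside 1000 permutations of gene positions on 9 of 20 chromosomes, and the largest distance from the median of all genes was 0.3491, on chromosome 13. Chromosome 13 was higher along its whole length, with medians of 0.34, 0.37 and 0.35 in its 3 parts, and chromosome 10 had a median of 0.22, while chromosomes 5 (-0.23), 8 (-0.20) and 9 (-0.17) were lower. The 2 libraries labelled PTEN-null had medians of 0.34 and 0.30 on chromosome 13, but both are ratios to the same control, so the values do not say whether the control or the other cells would carry the difference. The loss of collagen IV is more than such a difference could give, since Col4a1 and Col4a2 fell 64.1-fold and 95.2-fold while other tested genes within 0.5 Mb ranged from -0.16 for Ankrd10 to -1.14 for Irs2 among those named, with 2 unnamed gene models lower still and not past the test. No DNA data were analysed here, and regional control of expression was not tested as an alternative.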
